A study of Mus musculus with 8 samples.

How the data were processed

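RNA was measured in sorted bone marrow progenitors of 8 male mice, 4 with 2 intact Rpl11 alleles (WT) and 4 with 1 floxed allele (Rpl11_lox), all carrying a tamoxifen-activated Cre recombinase. Per the labels' protocols, total RNA of 2 to 8 ng was converted to cDNA with a low-input template-switching kit and amplified for 11 to 14 cycles, depending on each sample's yield. The sheared cDNA was then made into Illumina libraries with 8 further cycles. RNA integrity numbers ran from 7.5 to 9.3, with an average of 8.9. These are given as ranges and not per library. The kit does not mark strand, so overlapping genes on opposite strands cannot be told apart.

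The authors deposited 1 table of FPKM values (fragments per kilobase of transcript and 1000000 mapped fragments) with 23284 gene symbols and 8 columns. The submitters' processing notes name TopHat2 2.0.4, Bowtie 0.12.7, SAMtools 0.1.16, Cufflinks 1.3.0 and the mouse build GRCm38 (mm10), without their settings. The columns are headed WT and KO with replicate numbers, and KO was taken as Rpl11_lox. FPKM are not counts, so no count model was used. The fragments behind a value are unknown, and no counting interval is given. The lowest values give a rough idea of relative depth. The 1st percentile of FPKM times transcript length, over transcripts of 1000 to 4000 nt, lay between 0.0363 and 0.0483 in 4 libraries and between 0.0249 and 0.0291 in the other 4, so a single fragment counted for more in the former.

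Each library was divided by its median-ratio factor (0.865 to 1.14). A pseudocount of 1 was added, log2 was taken, and the 10278 genes with a mean of at least 1 scaled FPKM over the 8 libraries were tested. The test was limma's moderated test with an intensity trend and genotype as its only term, in R 4.3.3 with limma 3.58.1, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. Rpl11 was also compared by a two-sided exact permutation test over the 70 assignments of the libraries. Of 30 gene lists, the 23 with at least 5 tested members, leaving out the Y-linked genes, were tested with camera at a preset correlation between genes of 0.01. They were tested again with an estimated correlation, with fry and by exact permutation of the list means. Genes within 10 Mb of Rpl11 were compared with genes elsewhere by Fisher's exact test.

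The design, the lists, the alternative settings and the rule for named genes were fixed before the data were examined. The rule took Rpl11, and up to 12 genes per direction that passed with no overlap between genotypes. Where these fell short, it took up to 6 per direction by smallest unadjusted p with no overlap. It also took up to 4 members of each list by smallest p, and Trp53, Mdm2, Cdkn1a, Ccng1, Myc, Kit, Ly6a, Gata1 and Rpl5.

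Transcript lengths, GC content and coordinates came from GENCODE release M21 on GRCm38, which held 20887 of the symbols directly and 1914 through an older name. A length was found for 98.7% of the tested genes. After the libraries had been seen to differ by transcript length, 9 ways of allowing for this were tried, all chosen after seeing the data. They were a term for the 4 libraries with FPKM sums over 1000000, each library's slope on log2 length as a covariate, these 2 together, the first principal component, the mean of the ribosomal protein genes, a loess correction on length (span 0.3), that correction with the slope, and each set of 4 libraries alone. Rpl11 was also set against the mean of the other ribosomal protein genes.

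The method was tested on simulated data with 100 genes changed by a log2 of 1 and 100 by a log2 of 2 among 10278. Without a length structure, the genotype-only model recovered 77% and 98% of them. With the length structure of these libraries it recovered 17% and 66%, and the model with the length slope recovered 74% and 96%. With the slope, 7.61% of its calls were genes left unchanged. Simulated errors were independent between genes, and the changed genes were drawn only from the better expressed of those tested. The simulated length structure was built from the fitted slope model itself. The recovery with the slope therefore holds only for structure of that form. Figures were drawn with matplotlib.

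The same replicate numbers occur in both genotypes, and nothing in the labels ties equal numbers together. No pair of libraries held identical values, and all 8 were kept. No column of the table was left unused.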

Results

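The series profiled RNA from hematopoietic progenitors of adult mice that had lost part of their Rpl11, which encodes a protein of the large ribosomal subunit. Its title sets this loss against Diamond-Blackfan anemia, an inherited failure of red cell production, and lymphoma. Male mice of mixed background were fed tamoxifen for 20 weeks from 6 weeks of age, which activates the Cre recombinase, and were sampled at 26 weeks. Cells without lineage markers and positive for Sca1 and cKIT were sorted from bone marrow. There were 4 WT and 4 Rpl11_lox libraries, each from an independent animal, and the values were FPKM. The deposited FPKM summed to between 603441 and 2398760 per library, and the number of fragments behind them is unknown.

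The libraries differed most in their share of short transcripts. In WT 1, WT 4, Rpl11_lox 1 and Rpl11_lox 3, which had FPKM sums over 1000000, genes with transcripts of 300 to 700 nt lay 0.40 to 1.56 (log2, median) above their mean over the 8 libraries. In WT 2, WT 3, Rpl11_lox 2 and Rpl11_lox 4 the same medians ran from -1.18 to -0.70. The first principal component held 51.9% of the variance and the second 12.3%. Correlations of log2 values ran from 0.923 to 0.961 between libraries of the same set and from 0.857 to 0.933 between sets, across genes, which are not independent replicates. Each genotype had 2 libraries in each set, and for Rpl11 and the 13 lists called, values within the sets are given beside the pooled ones. The genotypes were not matched within the high-sum set. There the slopes on log2 transcript length were -0.41 and -0.32 in WT and -0.17 and -0.13 in Rpl11_lox. In the low-sum set they were 0.31 and 0.27 in WT and 0.31 and 0.14 in Rpl11_lox. Differences within a set can therefore still carry part of the length structure.

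**Figure D1:**
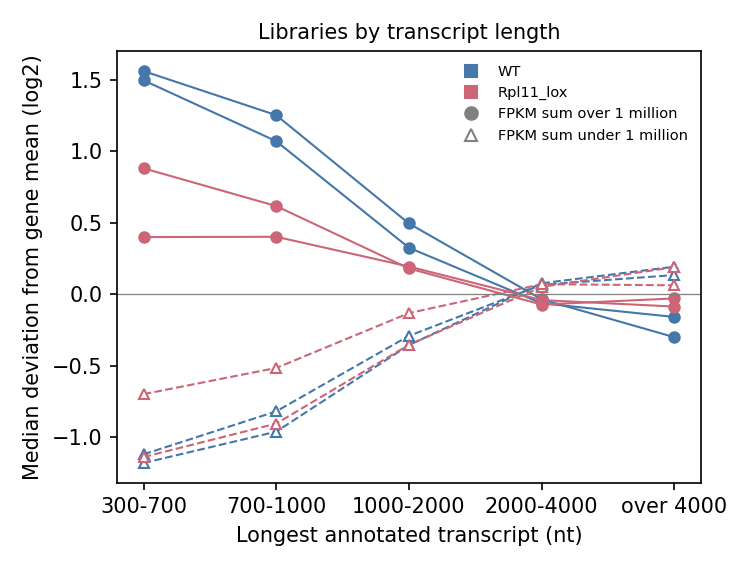
The horizontal axis gives the length class of the longest annotated transcript (nt) and the vertical axis the median deviation of its genes from their mean over all 8 libraries (log2), with a line per library. At 300 to 700 nt the 4 libraries with FPKM sums over 1000000 lie between 0.40 and 1.56 and the other 4 between -1.18 and -0.70.

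Rpl11 lies on chromosome 4 from 136028265 to 136053428 (GRCm38), on the minus strand. Its scaled FPKM was 22523, 1314, 1563 and 20573 in WT 1 to 4 and 6957, 827, 4236 and 1498 in Rpl11_lox 1 to 4. On the log2 scale the means were 12.44 ± 2.26 and 11.26 ± 1.40 (SD, n = 4 each), a difference of -1.18 that the spread between libraries exceeded (exact permutation test, two-sided, p = 0.371). Within the libraries with high FPKM sums the difference was -1.99, and within those with low sums it was -0.36. Against the mean of 78 other ribosomal protein genes in the same library, Rpl11 stood at 0.69 ± 0.57 in WT and -0.16 ± 0.33 in Rpl11_lox (log2, SD, n = 4 each). That ratio in Rpl11_lox was 0.557 of the WT ratio, with an exact permutation p of 0.0857. It was 0.472 within the high-sum libraries and 0.656 within the low-sum ones. In log2, the ratio was 1.19 and 1.17 in WT 1 and WT 4 (high-sum) and 0.187 and 0.196 in WT 2 and WT 3 (low-sum). The ratio thus varied with the library set as well. Permuted within the sets, the exact p was 0.0556, the smallest that 36 arrangements can give. This comparison with the other ribosomal protein genes was chosen after seeing the data. Rpl11 ranked 2 of 79 from the lowest by this difference in the high-sum set and 3 of 79 in the low-sum set. Rps27 and Rpl26 were also low, and ribosomal protein genes have near-identical pseudogenes that make such values uncertain. Which exons the lox sites flank is not given in the sources used here.

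**Figure D2:**
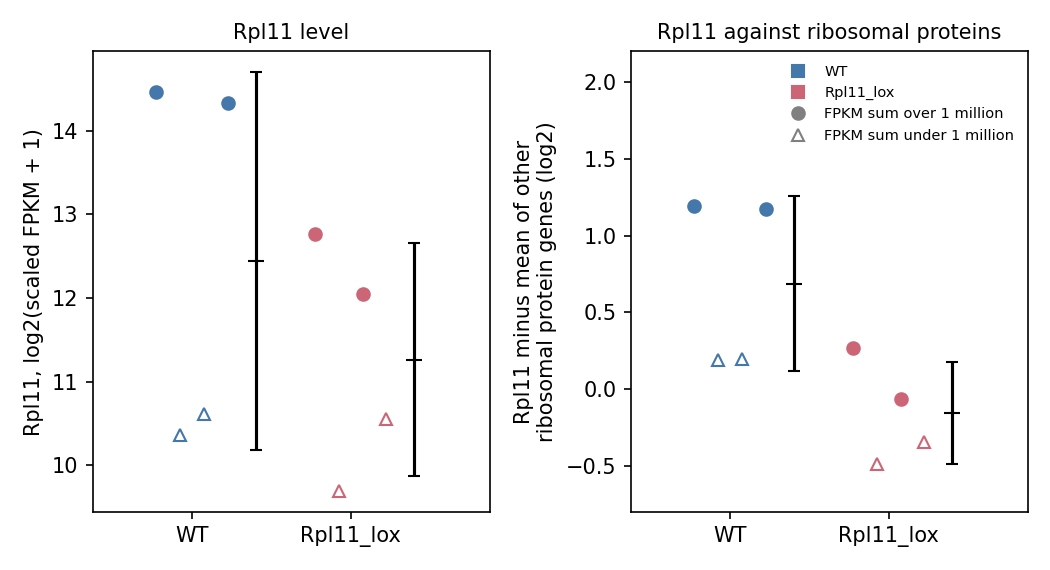
The left panel shows Rpl11 as log2(scaled FPKM + 1) and the right panel its log2 difference from the mean of 78 other ribosomal protein genes, with a point per library and bars for the mean and SD (n = 4). On the right, WT averages 0.69 and Rpl11_lox -0.16, and in each set of libraries both WT points lie above both Rpl11_lox points.

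No single gene passed the test across all genes. Of 10278 genes, limma called 0 at an adjusted p under 0.05, with a smallest adjusted p of 0.158, and 419 had an unadjusted p under 0.05 (212 higher and 207 lower in Rpl11_lox), where 513.9 are expected by chance. The 4 values of one genotype all lay above the 4 of the other for 333 genes, 3.24% of those tested, against 2.86% by chance. The genes named next are those with the smallest p and no overlap, and none passed in this fit. Among the higher ones, C2cd4a had 8.05 ± 4.67 scaled FPKM in WT and 136 ± 132 in Rpl11_lox (SD, n = 4 each), Plek2 0.726 and 3.83, 9030617O03Rik 1.60 and 5.85, and Pbx1, a homeodomain transcription factor, 3.10 and 5.99. Cdkn1a and Phlda3 belong to the p53 list. Among the lower ones, Ctse, an intracellular aspartic protease, had 104 ± 32.6 in WT and 23.2 ± 7.13 in Rpl11_lox, a log2 difference of -2.11 (SE 0.287). Hemgn, a hematopoietic nuclear protein, had 20.98 and 7.17, Aldh1a7 9.59 and 2.30, and Ephx2 6.61 and 2.38, and Rhd and Gypa belong to the erythroid list. The 9 ways of allowing for the library structure, chosen after seeing the data, called between 0 genes (library set and length slope together, and loess on length) and 31 (first principal component), with 8 for the library set and 23 for the length slope. Weighting the libraries by their fit called 1109 genes, with weights from 0.182 to 7.16 that rested mainly on WT 3 and Rpl11_lox 4.

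Erythroid genes were lower in Rpl11_lox. All 21 tested members of the erythroid list had lower means, with a median log2 difference of -0.68, and their average was 5.50 ± 0.319 in WT and 4.69 ± 0.375 in Rpl11_lox (log2, SD, n = 4 each). Rpl11_lox 3, at 5.24, lay within the WT range of 5.07 to 5.83. Rpl11_lox 1, 2 and 4 had 4.41, 4.61 and 4.50. With the length slope as a covariate, 19 of the 21 members were lower. Rhd, a blood group membrane protein, went from 167 ± 44.3 to 44.1 ± 9.60 scaled FPKM, and Gypa, the red cell sialoglycoprotein glycophorin A, from 15.2 ± 4.08 to 4.21 ± 0.984. Kel, another blood group protein, had 14.4 in WT and 7.46 in Rpl11_lox. Adjusted over the list alone, 5 members fell (Rhd, Gypa, Kel, Mfsd2b and the water channel Aqp1), and over all genes 0 did. Gata1, the erythroid transcription factor, had 101 ± 19.0 and 86.1 ± 28.8 and did not pass. The list was called by camera with a preset correlation (adjusted p = 7.1e-15), and not with an estimated one (adjusted p = 0.0515 with an estimated correlation, unadjusted p = 0.0081). The exact permutation p of the list average was 0.0571. It differed by -0.89 within the high-sum libraries and by -0.73 within the low-sum ones.

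Genes of heme synthesis and iron handling were lower as well, with 17 of 21 members lower and a median log2 difference of -0.54. Uros, which makes uroporphyrinogen III, fell from 28.0 ± 8.24 to 10.8 ± 1.93 scaled FPKM (SD, n = 4 each) when adjusted over the list alone, the only member to pass. Hmbs had 275 and 152, Ppox 35.3 and 20.3, and Alad 304 and 166, all enzymes of the same pathway. The list had an adjusted p of 8.6e-08 by camera with a preset correlation and an adjusted p of 0.0515 with an estimated correlation. The list average had an exact permutation p of 0.0286, the smallest that the 70 assignments can give, and differed by -0.51 within the high-sum and -0.42 within the low-sum libraries.

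Targets of p53, the transcription factor activated by ribosomal and DNA stress, were higher on average. Of 29 members, 20 had higher means, with a mean log2 difference of 0.32 and a median of 0.10. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 9.79 ± 2.05 to 35.4 ± 13.3 scaled FPKM (SD, n = 4 each), and Phlda3, a repressor of Akt signaling, from 8.94 ± 6.69 to 43.7 ± 24.6. These 2 passed adjusted over the list alone (limma adjusted p = 0.0065 and 0.0144), and 0 members passed over all genes. Psrc1 had 16.1 and 35.5 and Zmat3 0.707 and 2.05. Mdm2, which encodes the p53 ubiquitin ligase, had 8.92 ± 2.33 and 10.4 ± 2.12, Ccng1 12.9 ± 4.98 and 23.3 ± 9.38, and Trp53 itself 222 ± 56.8 and 241 ± 55.3, and none of these passed. Camera gave an adjusted p of 3.9e-04 with a preset correlation and an adjusted p of 0.0549 with an estimated correlation. The exact permutation p of the list average was 0.0286. The average was higher by 0.185 within the high-sum libraries and by 0.45 within the low-sum ones, and with the high-sum libraries alone camera did not call it (adjusted p = 0.375).

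DNA replication genes were lower and immediate early genes higher. Of 28 replication genes, 26 had lower means, with a median log2 difference of -0.35. Ccne1, which encodes cyclin E1, had 65.7 ± 14.6 in WT and 31.5 ± 9.15 in Rpl11_lox (SD, n = 4 each), the helicase subunit Mcm7 182 and 128, and Mcm10 20.0 and 14.0, while the polymerase subunit Pola1 had 2.86 and 4.79. None passed over the list alone. Camera gave an adjusted p of 2.5e-07 with a preset correlation and an adjusted p of 0.0515 with an estimated correlation, and the exact permutation p was 0.0286. Within the sets the average differed by -0.28 (high-sum) and -0.38 (low-sum), and camera did not call it in the high-sum libraries alone (adjusted p = 0.082). Of 20 immediate early genes, which respond quickly to stimulation or cell handling, 17 had higher means, with a median of 0.34. Nr4a1 had 13.7 ± 10.7 and 38.0 ± 20.5, Nr4a2 1.62 and 2.83, and Atf3 7.54 and 18.03, and no member passed over the list alone. The adjusted p was 6.2e-06 with a preset correlation and 0.0515 as an adjusted p with an estimated correlation, and the exact permutation p was 0.0857. Within the sets the average differed by 0.45 (high-sum) and 0.38 (low-sum).

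**Figure D3:**
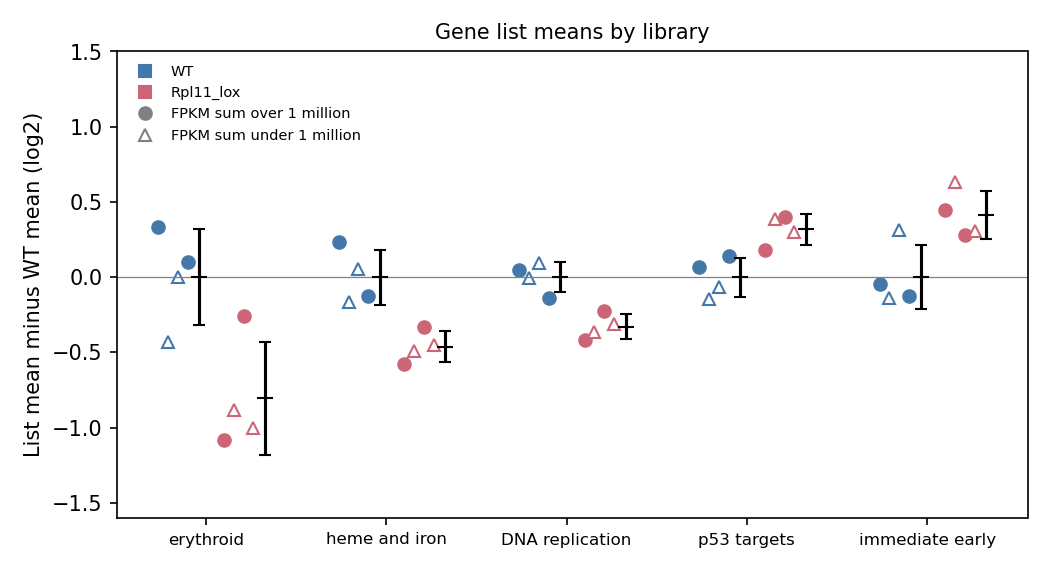
Each point is the average log2 value of a gene list in a library, less the WT mean of that list, with bars for the mean and SD (n = 4). The erythroid average is 4.69 in Rpl11_lox and 5.50 in WT before this subtraction, and in the heme and iron, DNA replication and p53 lists the genotypes do not overlap.

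Camera with a preset correlation called 13 of the 23 lists, 7 higher and 6 lower, and with an estimated correlation 0, with 6 at an unadjusted p under 0.05. Fry called 5 (erythroid, heme and iron and DNA replication lower, p53 targets and immediate early higher), and exact permutation of the averages called 0, where the smallest p that 70 assignments allow, 0.0286, can hardly pass adjustment over 23 lists. Among the other lists called higher were dendritic and MHC class II (8 of 9 members higher, with H2-Aa at 0.818 in WT and 2.39 in Rpl11_lox), stem cell (16 of 18, with Slamf1 at 1.17 and 2.39 but Mllt3 lower, at 4.06 and 2.62), megakaryocyte (15 of 17, with Thbs1 at 0.715 and 2.16), myeloid progenitor (21 of 23) and integrated stress response genes (16 of 20). Their adjusted p values with an estimated correlation were 0.0549, 0.159, 0.159, 0.555 and 0.222. Within the high-sum libraries their averages differed by 0.26, 0.12, 0.07, 0.012 and 0.03, and within the low-sum ones by 0.58, 0.27, 0.50, 0.47 and 0.26. The stem cell call was lost without WT 1 (camera adjusted p = 0.0981). The myeloid progenitor call was lost without WT 1, WT 3, Rpl11_lox 1 or Rpl11_lox 4, with average differences of 0.22, 0.09, 0.019 and 0.18 (camera adjusted p = 0.0845, 0.38, 0.72 and 0.139). The integrated stress call was lost without WT 2, WT 3, WT 4, Rpl11_lox 2 or Rpl11_lox 4 (camera adjusted p = 0.0722, 0.147, 0.078, 0.0699 and 0.198). Ribosomal proteins other than Rpl11 (77 of 78 lower), oxidative phosphorylation (62 of 63) and histone genes (18 of 19) were called lower, with adjusted p values of 0.769, 0.65 and 0.581 with an estimated correlation. These lists hold short transcripts, and their averages differed by -0.91, -0.74 and -1.02 within the high-sum libraries and by 0.24, 0.12 and -0.08 within the low-sum ones, so the direction of the first 2 turned between the sets. Each of these 3 calls was lost without WT 1, WT 4, Rpl11_lox 2 or Rpl11_lox 4, with camera adjusted p values from 0.139 to 0.682. Ribosome biogenesis, Myc target, lymphoid priming, neutrophil, monocyte and macrophage, mast cell and basophil, mitosis, interferon, NF-kB and glycolysis genes were not called. Myc had 93.7 ± 23.1 and 126 ± 19.6 scaled FPKM, Kit 22.1 ± 8.80 and 23.6 ± 4.21, Ly6a 3.34 ± 3.29 and 4.27 ± 2.38, and Rpl5, whose protein binds Rpl11, 665 ± 383 and 526 ± 161 (SD, n = 4 each), and none of these passed.

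The mice were of mixed background, and genes linked to the floxed allele could differ by strain. Of 182 tested genes within 10 Mb of Rpl11, 8 (4.40%) had an unadjusted p under 0.05, against 4.07% of 9943 genes elsewhere (Fisher's exact test, two-sided, p = 0.708). Rhd, at 134864536 to 134896172 on chromosome 4, lies within this window.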

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

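Of the tests in this part, those of normalization and genotype for the library sets, all those of the erythroid and heme lists, the tests of length and of cell shares for the p53 list, and the splits for the erythroid and p53 averages were chosen only after the result was seen, and so were the models with the length slope or the library set.

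In 11 of 156 groups of 4 libraries, 1 library lay far from the other 3, and about 5% are expected by chance for normally distributed values. Genes were judged on scaled FPKM without log2, where high values stand out more, so that share is only a rough guide. In Rpl11_lox 3, C2cd4a was at 332.5 scaled FPKM (51.0 to 86.2 in the others), Phlda3 at 80.4 (29.1 to 34.8) and Psrc1 at 55.8 (26.9 to 29.8), and the Myc target average was 7.51 (7.16 to 7.19). Phlda3 was at 18.9 in WT 1 (4.55 to 6.18). In WT 3, Nr4a1 was at 29.7 (7.87 to 8.71) and Slamf1 at 0.805 (1.27 to 1.301). In Rpl11_lox 2, Nr4a2 was at 4.05 (2.29 to 2.52) and Thbs1 at 4.00 (1.40 to 1.74). Ly6a was at 8.26 in WT 4 (1.42 to 1.92), and the interferon average was 2.74 in Rpl11_lox 1 (2.32 to 2.39).

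The 4 libraries with high FPKM sums had more signal from short transcripts. Normalization by effective length would raise the worth of 1 fragment at short lengths. That worth differed between the sets by -0.0812 (log2) between 700 to 1000 and 1000 to 4000 nt. The FPKM themselves shifted by 1.56 there, which argues against this cause at these lengths. The class of 300 to 700 nt, where library medians ran from -1.18 to 1.56, was left out of the test, so the cause stays open there. Genotype cannot split the libraries in this way, since 2 of the 4 with high sums are WT. GC content also fails as the cause, since 102% of the difference in length slope remained with it in the model. RNA integrity and cDNA amplification stay open, as the labels give only their ranges.

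The erythroid and heme genes were lower in Rpl11_lox. Length structure as the whole cause is argued against by a median of -0.63 (log2, 42 genes) with the length slope as a covariate. Hba-a2 and Hbb-b2 together reached at most 0.248 of Rhd in the low-sum WT libraries. This argues against mature red cells as a large part of those libraries only. Short transcripts are lowered in them, with medians of -1.18 and -1.12 (log2) at 300 to 700 nt, so the ratio may understate globin RNA. In the high-sum WT libraries, where short transcripts are raised, the ratio reached 3.31 and does not decide. No other globin genes were counted. Fewer erythroid-committed cells and lower expression per cell cannot be told apart in RNA of many cells together. The folds of the members spread 1.17 times their median SE. That ratio does not decide it, since the log2(value + 1) scale understates changes of low members and so alters the spread. The sort for cells without lineage markers and with Sca1 and cKIT should remove mature red cells and erythroid-committed cells, and its purity was not measured here. Yet RNA of the erythroid transcription factors Klf1 and Gata1 averaged 328 and 93.3 scaled FPKM over the 8 libraries. Ly6a, the gene of Sca1, averaged 3.81. The gate is therefore no argument against a difference in the share of erythroid cells. Chance cannot be excluded for the size of the erythroid average with the slope as a covariate, since 2 of the 35 splits, the real one included, gave as large a value (0.759 for genotype, 0.914 for the highest other).

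The p53 targets were higher in Rpl11_lox. With the length slope as a covariate their mean fold was 0.33 (log2, SE 0.108 over the members, which are not independent replicates) and their median 0.13. Without it the mean was 0.32 and the median 0.10. Neither shrank, which argues against length structure, as far as the slope captures it, as the whole cause of the higher average. The median is small, so the average rests on part of the members. Handling stress stays open, as the mean fold was 0.36 (SE 0.144) with the immediate early average as a covariate. So does a lower share of erythroid cells, as the list exceeded the highest of 4 other lineage lists by only 0.0346. The same sort should remove such cells, though Klf1 and Gata1 RNA was present. With the slope as a covariate, 1 of the 35 splits, the real one, gave as large an average, with 0.330 for genotype and 0.311 for the highest other. This is the smallest share that 35 splits can give, for 1 of 23 lists and a covariate chosen after seeing the data. Camera's p with the covariate, adjusted over the lists, was 0.234 (estimated correlation), so chance is left open.

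The counts of calls were set against the 35 splits of the 8 libraries. For the 0 genes of the planned test the comparison is void, since all 35 splits reach a count of 0 by definition. The highest other, 4078, belongs to the split by FPKM sum, a structure of the libraries. Chance cannot be excluded for the 13 lists of camera with a preset correlation, since 5 splits, the real one included, gave as many and the highest other gave 17. The 1109 genes found with array weights were reached by 18 splits, the real one included, with 4446 for the highest other. With the length slope as a covariate, 1 split, the real one, gave 23 genes and the highest other 3. This is the smallest share that 35 splits can give. It makes no allowance for the choice of this model among 9 corrections after seeing the data, so chance is left open. With set and slope together or with loess 0 genes passed, though the fold of gene Rhd hardly moved (-1.85 with the slope, -1.88 with both and -1.81 with loess, where its adjusted p was 0.0614). Rhd does not stand for all 23 genes. Their limma adjusted p with loess ran from 0.0614 to 0.88 (Fads2). With the library set as a term, 18 splits are too few for a share under 0.05, with 8 genes for genotype (1 split) and 2 for the highest other.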

How the results depend on the processing

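The allowances for library structure, the 4-library fits, the filter on transcripts under 300 nt and the exact test of list averages were chosen after seeing the data; the other alternatives were chosen before. The cause was not tested except where given. Under the settings chosen in advance other than leaving out a library, named single genes stayed on the same side of the threshold and in the same direction in 560 cases, passed in 36, all with array weights, and reversed in 4. Among the added ones these counts were 439, 65 and 5. Fragment numbers are unknown, so no limit from depth can be given for single genes.

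The number of genes changed (0) became 1109 with array weights (560 higher and 549 lower), where WT 3 and Rpl11_lox 4 held weights of 6.40 and 7.16 and the folds of the called genes followed those of the low-sum libraries (r = 0.975, across genes). It became 1 with an ordinary linear model. It was 8 with the library set as a term, 23 with the length slope, 0 with both, 31 with the first principal component, 22 with the ribosomal protein mean, 0 with loess on length, 23 with loess and slope, and 15 in either set of libraries alone. Leaving out 1 library gave 0 to 2 genes, with 2 without WT replicate 2 and 1 without Rpl11_lox replicate 4.

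The 13 lists called became 0 with an estimated correlation, 5 with fry, 1 with fry's mixed test, 0 by exact permutation, which can hardly pass adjustment with 8 libraries, and 6 in the high-sum libraries alone. Leaving out 1 library gave 8 to 19, with 8 without Rpl11_lox replicate 4.

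The Rpl11 difference (-1.18, limma unadjusted p = 0.36) stayed negative in every alternative run but nearly vanished with array weights (-0.0837, unadjusted p = 0.878), and was -0.37 in the low-sum libraries alone. It passed at an unadjusted p under 0.05 with the library set (-1.18), the slope (-0.74), both (-0.77), the first principal component (-0.66), the ribosomal protein mean (-0.74), loess and slope (-0.74) and in the high-sum libraries alone (-1.90). It was -0.51 to -1.87 with 1 library left out. Relative to the other ribosomal protein genes it moved by less than the smaller SD within a genotype (0.333), with -1.01 to -0.68 when 1 library was left out.

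The share of genes near Rpl11 with an unadjusted p under 0.05, less that elsewhere (0.32 percentage points), turned negative at a pseudocount of 0.1 (-0.15), with upper-quartile scaling (-1.05), quantile normalization (-0.21), robust limma (-0.24), array weights (-1.11), the replicate block (-1.21), the library set (-0.28), set and slope (-0.91), the high-sum libraries (-1.10) and without transcripts under 300 nt (-0.11). It ran from -1.28 to 1.98 with 1 library left out, and no alternative passed the test.

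Reversed single values were small for genes. With array weights, Trp53 was -0.12, Kit -0.19 and Rpl5 0.28. In the low-sum libraries they were -0.0499, -0.13 and 0.19. Rpl5 was 0.10 with quantile normalization and 0.00272 with the first principal component, and Kit was -0.0193 with set and slope. With 1 library left out, Trp53 ran from -0.0181 to 0.30, Kit from -0.14 to 0.36 and Rpl5 from -0.47 to 0.10. The ribosomal protein list average reversed to 0.00569 with quantile normalization, 0.47 with array weights, 0.000184 with the slope, 0.0573 with the first principal component, 0.00288 with loess and slope and 0.24 in the low-sum libraries. Oxidative phosphorylation was 0.23 with array weights and 0.11 in the low-sum libraries, and histone genes 0.14 with array weights. Ribosome biogenesis was -0.0679 with array weights and -0.0129 in the low-sum libraries, Myc targets 0.10 with quantile normalization, and mitosis 0.10 in the high-sum libraries. With 1 library left out, the ribosomal protein list ran from -0.85 to 0.17, oxidative phosphorylation from -0.69 to 0.0706, Myc targets from -0.13 to 0.0546, ribosome biogenesis from -0.0281 to 0.12, lymphoid priming from -0.0160 to 0.17 and neutrophil genes from -0.0551 to 0.61.

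The first principal component held 41.2% of the variance over the 500 most variable genes. For replicate numbers 1 to 4, the deviations of the WT and Rpl11_lox libraries correlated at 0.416, 0.588, -0.371 and -0.265. Among the 8 libraries, 1 correlated best with its own number. The positive values belong to numbers with both libraries in the same set, and the negative ones to numbers split between the sets. They follow the library sets, so they cannot show whether equal numbers were handled together. With the replicate block, 0 genes and 12 lists were called.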

Other observations

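With the length slope as a covariate, an adjustment chosen after seeing the data, 23 genes passed limma, 4 higher and 19 lower in Rpl11_lox, and 8 of them also passed with the library set as a term. With both adjustments in 1 model, 0 passed. Beyond the genes already described, Sphk1, a sphingosine kinase, had 115 scaled FPKM in WT and 38.0 in Rpl11_lox, Stard10 200.1 and 64.5, Cldn13 146 and 40.5, and Rpl22l1, a paralog of the ribosomal protein gene Rpl22, 852 and 226. Serpina3g had 12.7 and 34.9 and Cap1 11.8 and 31.0. Some of these means hide the library sets. Rpl22l1 had 1566 and 1440 in WT 1 and WT 4 but 193 and 210 in WT 2 and WT 3. Cap1 had 4.12 and 5.56 in WT 1 and WT 4 but 19.0 and 18.5 in WT 2 and WT 3. The values of Rpl22l1, Cap1 and Cldn13 overlapped between genotypes. All genes named in this paragraph were picked by this fit after their values were seen, and none passed in the planned test.

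Lists with under 5 tested members were not tested. The T and NK cell list had 2 tested members, with Gzmb at 0.951 and 3.25 and Lat at 25.8 and 52.6 scaled FPKM in WT and Rpl11_lox, and Gzmb is also in the mast cell list. The B cell list had 3, the plasma cell list 3, the stroma and endothelium list 4, the Notch list 4 and the mitochondrially encoded list 0, and the Y-linked list had 2. Cd74, an MHC class II chaperone, had 4.03 ± 1.69 and 8.99 ± 5.27, and Cd48 46.6 ± 12.5 and 74.8 ± 19.6 (SD, n = 4 each).

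Ly6a, the gene of the Sca1 protein used in the sort, had between 1.42 and 8.26 scaled FPKM in the 8 libraries, while Kit had between 10.2 and 30.1. Mpo averaged 2754 and Elane 6127, both granule proteins of myeloid cells, and Klf1, an erythroid transcription factor, 328. Procr and Mecom, stem cell genes, averaged 0.498 and 0.803, under the limit of 1 for testing. Procr had 0.790 ± 0.545 in WT and 0.206 ± 0.322 in Rpl11_lox, and Mecom 0.812 ± 0.596 and 0.794 ± 0.376 (SD, n = 4 each). Neither was higher in Rpl11_lox, unlike most tested stem cell genes.

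The fold changes of 9595 genes in the 4 high-sum libraries and in the 4 low-sum libraries correlated at r = 0.145 across genes, which are not independent replicates, and 50.2% had the same direction. Each set alone called 15 genes, of which 12 and 10 were under 300 nt, and the only gene called in both differed in direction.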
